A study of Mus musculus with 14 samples.

How the data were processed

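RNA from the liver of 14 mice was sequenced, 7 fed a high fat, high sucrose diet (HFHS) and 7 fed a low fat, low sucrose diet (LFLS), with 1 library per mouse. Per the labels' protocols, total RNA was extracted with Tri Reagent and treated with DNase, polyadenylated RNA was made into TruSeq libraries, and single reads were sequenced on a HiSeq2000. The labels do not say that the kit kept strand, so reads of overlapping and antisense genes cannot be told apart. Strain, sex, age, length of feeding and time of collection were not given in the sources used here. The p-values reflect the spread between separate mice, which in tests without a block includes differences between the title numbers described below.

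Per the submitters' processing notes, CASAVA 1.8, Bowtie, TopHat and DESeq were used with the mouse genome build mm9. The counting tool, the annotation release and the other versions are not given in the sources used here. The deposited table of counts held whole numbers for 37681 Ensembl genes in 14 libraries. The authors' count for a gene was never below 1, and 11120 genes stood at 1 in every library, as if 1 had been added to each count. The authors' deposited results table gave signal values, means of counts divided by DESeq size factors over all libraries and over 2 groups, per the file headers. It also gave the authors' fold change, a ratio of 1 group mean to the other, and the authors' log2 of that ratio. The authors' p-value and adjusted p-value columns were from DESeq, per the file headers, and the adjusted values appeared rounded. The first of the authors' groups was identified as LFLS because its deposited means lay a median of 0.000299% from LFLS means recomputed from the counts, against 14.4% for HFHS means. Only the counts entered the tests, and the authors' table was used for gene names and for a comparison of called genes. Of the Ensembl identifiers 105 had no name in that table, and 330 symbols belonged to more than 1 identifier, of which the one with the highest total kept the plain symbol.

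The libraries held 18.2 M to 52.8 M counts (M, mega), with a median of 29.3 M. No gene took more than 8.78% of a library, and libraries of the same diet correlated at 0.933 or more on log2 CPM without any duplicated column. Samples were named by diet and a number within the diet. The first number of the sample title (1 or 2), whose meaning the labels do not give, was treated as a batch because libraries sharing it deviated together. Deviations from the diet means correlated at a mean of 0.129 between libraries of the same first number on different diets and at -0.134 between libraries of different first numbers.

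Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling and edgeR's default filter on low counts by diet group, which kept 17223 genes. The quasi-likelihood F test compared HFHS with LFLS without covariates, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change was its size divided by the square root of F. Values per group are means of TMM-scaled CPM with the standard deviation. The genes named in the text are the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 1 CPM in the higher group and all 7 libraries of that group above the median of the other. Up to 4 members of each gene list with the smallest p, the 5 most abundant genes and the 6 genes with the smallest p were named too. Any other gene is said to have been chosen after its values were seen, and results of some genes are not reported here.

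The 28 gene lists were fixed from textbook knowledge of liver metabolism, liver cell types and tissues that dissection can carry over. Of their 653 symbols 652 matched an identifier. Per library, a list's score was the mean log2 CPM (prior count 2) of its measured members, and lists needed at least 5 of them. The difference between diets was tested by exact permutation over all 3432 regroupings, where the smallest possible p is 0.000583, with Benjamini-Hochberg adjustment over 28 lists. With the title number as a block 1400 regroupings were possible. Besides calls over all genes, members were counted after adjustment over the list alone. The tests, the gene lists, the naming rule and most other settings were fixed before the data were examined.

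Other settings tried for genes were DESeq2 1.42.0, limma 3.58.1 voom with quality weights, RLE size factors, library totals alone, no filter, a filter of at least 1 CPM in at least 7 libraries and a test against a fold change of 1.2. They also covered the title number as a block, the 7 pairs of titles as a block, each title number alone and leaving out each library in turn. For the lists they were camera with an estimated correlation, other scalings, a prior count of 0.5, the median over members, the stricter filter, the pairs and leaving out each library. Chosen after seeing the data were the subtraction of 1 from every count and the 7 libraries with an exocrine pancreas score at or below 0. The correction for GC content and transcript length, the title number settings for lists and lists without shared members were also chosen after seeing the data. The correction took a lowess trend of each library's log2 deviations on GC content and then on transcript length, from the longest transcript of GENCODE M21, and covered 16351 of the tested genes (94.9%). The genome build of that annotation differs from mm9, and it was used for names, GC content and length only.

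The procedure was tested on simulated data in 10 simulations with 200 changed genes each. It recovered 19.2% of genes changed by 0.5 on the log2 scale, 73% at 1, 97.4% at 2 and 99.4% at 3, and 4.11% of calls fell on unchanged genes. A list shifted as a whole by 1 on the log2 scale was called in 10 of 10 simulations, lists over unchanged genes in 0 of 280 tests, and other lists 5 times in all. Simulated counts were independent between genes and had no difference between title numbers. These rates therefore need not hold for the real libraries or for smaller list shifts. An imposed GC trend with a slope of 0.0466 was left at 0.000288 after its removal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.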

Results

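Liver gene expression was measured in 14 mice by sequencing polyadenylated RNA. The design asked how liver transcript levels differed between 7 mice on a high fat, high sucrose diet (HFHS) and 7 mice on a low fat, low sucrose diet (LFLS). Each library came from a separate mouse, so the p-values measure spread between animals. Total counts per library ranged from 18.2 M to 52.8 M (M, mega), with a mean of 33.7 M ± 11.8 (SD, n = 7) in LFLS and 29.7 M ± 9.48 (SD, n = 7) in HFHS. The table held 37681 genes, of which 11120 stood at a count of 1, its lowest value, in all 14 libraries and 17223 were expressed highly enough to be tested. Sample titles began with the number 1 in LFLS 1 to 4 and HFHS 1 to 4 and with the number 2 in LFLS 5 to 7 and HFHS 5 to 7. The labels do not say what this first number marks, and it was treated as a batch, with values within each number given beside the pooled ones for list scores and most called genes. In tests without this number as a block, the spread between animals includes differences between title numbers. The X-linked transcript Xist, which marks female cells, had 4 to 13 counts per library, and the Y-linked gene Ddx3y had 995 to 5983. Both were chosen after values of the sex-biased genes were seen.

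The libraries differed along 2 main axes. The first principal component held 30.3% of the variance and placed LFLS 1 to 4 at -73.1 to -25.6, LFLS 5 to 7 at 30.8 to 35.9 and the HFHS libraries between -8.64 and 30.0. The second component held 17.6%, with HFHS 1 highest at 56.8. The correlation of a gene's deviation in a library with its GC content ran from 0.68 in LFLS 1 to -0.53 in HFHS 7. Mitochondrially encoded transcripts took from 1.39% of the counts (95% Wilson interval 1.39 to 1.40%) in LFLS 1 to 5.10% (5.09 to 5.11%) in HFHS 2. Exocrine pancreas transcripts took from 0.00156% (0.00144 to 0.00169%) in HFHS 6 to 0.186% (0.184 to 0.188%) in LFLS 2, and the intervals cover counting error only.

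**Figure D1:**
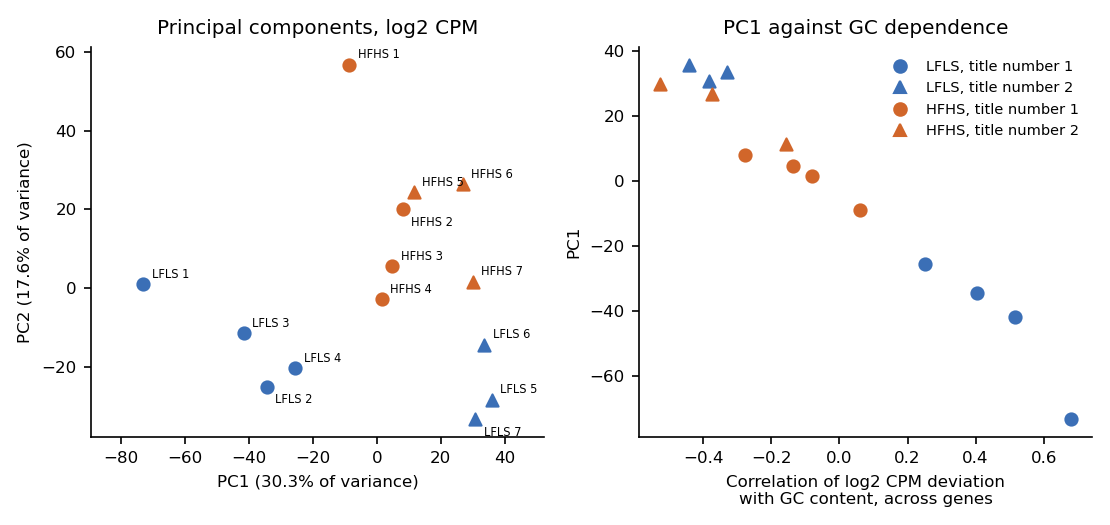
Principal components of log2 CPM over the tested genes and the correlation of expression with GC content, per library, coloured by diet with a separate marker for each title number. LFLS libraries of the numbers 1 and 2 lie at opposite ends of the first component, while HFHS libraries lie between -8.64 and 30.0.

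Genes of drug metabolism, lipid uptake and lipid storage were among the steepest increases on HFHS. Cyp2b9 (ENSMUSG00000040660), a cytochrome P450 of the 2B subfamily, rose from 0.177 ± 0.105 CPM (SD, n = 7) to 68.6 ± 97.5 CPM (SD, n = 7), a log2 fold change of 8.56 ± 1.24 (SE). Its HFHS libraries spanned 1.32 to 272 CPM, and no LFLS library exceeded 0.320 CPM. The related Cyp2b10 (ENSMUSG00000030483), a classical target of the constitutive androstane receptor, rose by 3.02 ± 0.57 (log2, SE), from 0.607 ± 0.472 to 4.81 ± 4.04 CPM. Reads of such closely related genes can be shared, so the division of signal between them is uncertain. Vldlr, the receptor for very low density lipoprotein, rose by 2.35 ± 0.49, and Mogat1, a monoacylglycerol acyltransferase of triglyceride synthesis, by 2.01 ± 0.35. Themis (ENSMUSG00000049109), a protein of T cell development, rose from 2.05 ± 0.781 to 22.1 ± 10.6 CPM, and the potassium channel gene Kcnb2 (ENSMUSG00000092083) from 2.32 ± 0.944 to 15.3 ± 3.42 CPM. Log2 changes were 3.44 ± 0.34 for Themis, 2.71 ± 0.26 for Kcnb2, 2.09 ± 0.22 for the actin-binding protein gene Nebl and 2.03 ± 0.16 for 9130409I23Rik. A4gnt rose by 3.41, Slc22a26 by 2.24, Als2cr12 by 2.07 and Tmprss11f by 2.01 on the log2 scale. Raet1d, a ligand of the NKG2D receptor from a family of similar genes, rose by 1.98 ± 0.24.

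These 12 largest increases had adjusted p values from 2.46e-05 (9130409I23Rik) to 0.0219 (Vldlr) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Raet1d had 0.00113. All 12 calls were kept when any 1 library was left out. In 10 of the 12 genes every HFHS library lay above every LFLS library. Cyp2b9 rose by 8.96 among title number 1 libraries and by 8.04 among number 2 libraries, and the corresponding values were 3.22 and 3.78 for Themis, 2.30 and 3.48 for Kcnb2, 3.97 and 2.58 for Cyp2b10, 1.99 and 3.05 for Vldlr and 1.87 and 2.26 for Mogat1. They were 2.09 and 2.10 for Nebl, 2.04 and 2.04 for 9130409I23Rik, 3.73 and 2.90 for A4gnt, 2.40 and 2.16 for Slc22a26 and 2.26 and 1.59 for Raet1d. Without HFHS 1 the Cyp2b9 change was 7.57. With limma voom and quality weights the Cyp2b9 change was 7.08, at an adjusted p of 0.0658 in limma's moderated test against a range of 1.24e-14 to 0.231 over all alternatives.

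Among the decreases, Moxd1 (ENSMUSG00000020000), a monooxygenase related to dopamine beta-hydroxylase, fell from 76.1 ± 74.7 CPM (SD, n = 7) to 1.00 ± 0.874 CPM (SD, n = 7), a log2 change of -6.29 ± 0.87 (SE). The fatty acid-binding protein gene Fabp5 (ENSMUSG00000027533) fell from 78.4 ± 38.9 to 14.5 ± 6.88 CPM, a change of -2.43 ± 0.40. The acid phosphatase gene Acpp changed by -1.86 ± 0.23, the adenylyl cyclase gene Adcy1 by -2.44 ± 0.41 and the zinc finger gene Ikzf4 by -2.32 ± 0.39. The log2 change was -2.83 for 3930402G23Rik and -2.18 for Gm15998. Gpr110, an adhesion receptor gene, changed by -2.85 ± 0.59, the trefoil factor gene Tff3 by -2.57 ± 0.59, the ferritin receptor gene Scara5 by -2.24 ± 0.51 and Onecut1, which encodes the hepatocyte transcription factor HNF6, by -2.10 ± 0.52. Gm8815 and Gm20530 overlap and carried nearly the same counts, with log2 changes of -2.70 and -2.69, so which of them fell is uncertain.

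Adjusted p values of these decreases ran from 0.00113 (Acpp) to 0.0439 (Onecut1) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 12 largest decreases 6 kept their call without any 1 library, and in 3 of 12 every HFHS library lay below every LFLS library. Gpr110 lost its call without HFHS 2, 5 or 6, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p values of 0.0539 to 0.0601. Scara5 lost it without HFHS 2, 5, 6 or 7 or LFLS 4, 5 or 7 (0.0531 to 0.0785), and Tff3 without HFHS 1, 2, 3, 5, 6 or 7 or LFLS 2, 4, 5 or 7 (0.0503 to 0.0818). Onecut1 lost it without HFHS 1, 2, 4, 5, 6 or 7 or LFLS 3 to 7 (0.0542 to 0.104), and Gm8815 without any 1 HFHS library or LFLS 2, 3 or 7 (0.0596 to 0.0969), with Gm20530 alike (0.0602 to 0.0977). Moxd1 changed by -5.74 among number 1 libraries and by -6.89 among number 2 libraries, and Fabp5 by -2.05 and -2.93. The values within number 1 and number 2 were -1.71 and -4.05 for Tff3, -1.33 and -3.26 for Scara5, -2.04 and -3.82 for Gpr110, -1.66 and -2.92 for Onecut1 and -3.33 and -1.93 for 3930402G23Rik. Acpp changed by -1.76 and -2.02, Adcy1 by -2.10 and -2.62, Ikzf4 by -2.06 and -2.62 and Gm15998 by -2.06 and -2.48. Without HFHS 4 the Tff3 change was -3.30. All 24 of the largest changes had the same sign within both title numbers, as did all 481 called genes measured in both, against 50.7% of other genes. These genes were picked from the pooled fit of the same libraries, so the choice favours this agreement and it is not a replication.

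**Figure D2:**
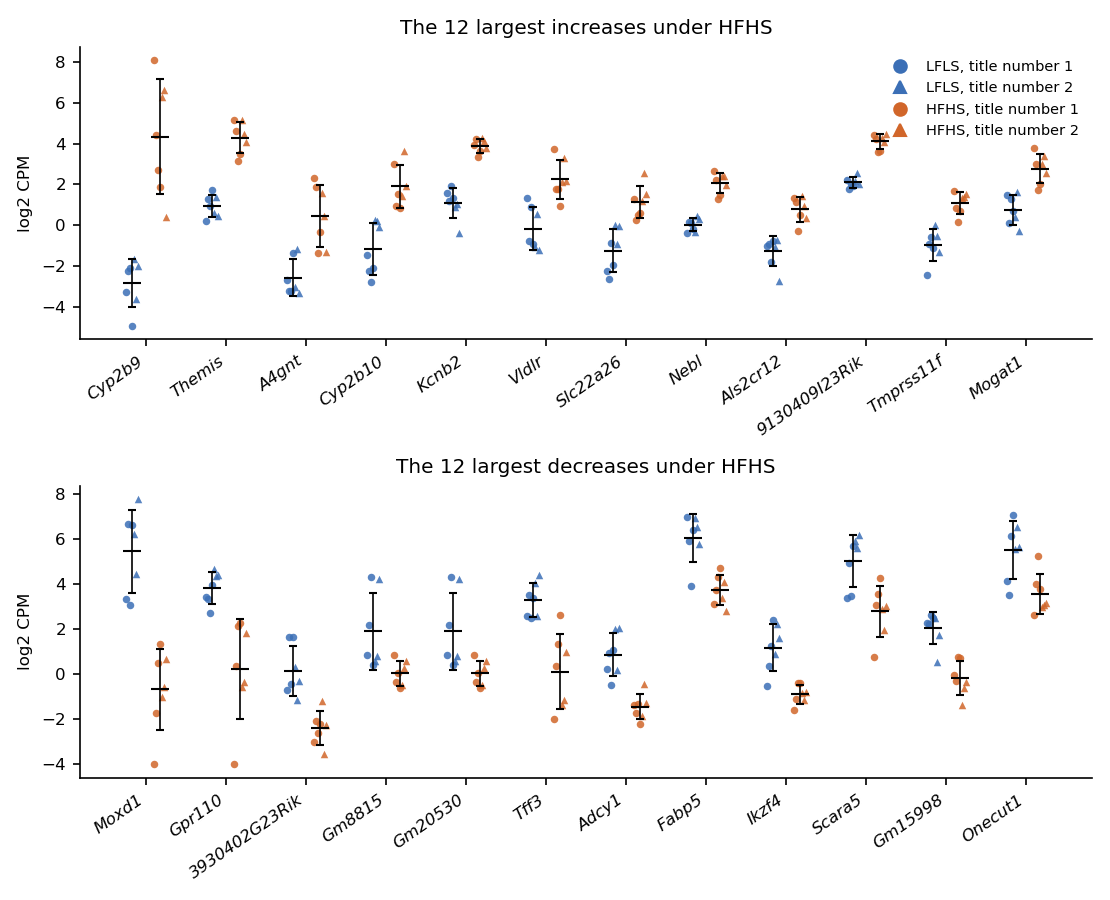
Log2 CPM of the 12 largest increases and 12 largest decreases per library, with group means, for 7 LFLS and 7 HFHS livers. In 10 of the 12 increases all HFHS points lie above all LFLS points, and in 3 of the 12 decreases all lie below.

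In all, 484 of 17223 genes changed with diet by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 236 higher and 248 lower on HFHS. Changes reached at least 2-fold for 88 of the higher and 53 of the lower genes. In 202 of the 484 genes the 2 diets did not overlap. Over all 17223 tested genes 284 (1.65%) did not overlap, where chance gives 0.0583% for a single gene. With the title number as a block 1540 genes changed (755 higher, 785 lower), and all 484 were among them. Within number 1 libraries (n = 4 per diet) 1484 genes changed and within number 2 libraries (n = 3 per diet) 269, of which 267 and 102 belonged to the 484. With library totals alone the split was 379 higher and 152 lower, 71.4% higher in place of 48.8%. The number fell to 133 without HFHS 2, 176 without HFHS 5, 199 without HFHS 6, 248 without HFHS 1 and 252 without HFHS 7. It was 262 without LFLS 4, 263 without LFLS 2, 275 without LFLS 7, 316 without LFLS 3 and 853 without LFLS 6. Among the 7 libraries whose exocrine pancreas score was below 0 (3 LFLS and 4 HFHS), a setting chosen after seeing the data, 6 genes passed, including Kcnb2, Raet1d, Fabp5 and Acpp.

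The most abundant transcripts of the liver did not pass edgeR's test. Albumin (Alb) stood at 73550 ± 15466 CPM (SD, n = 7) on LFLS and 70663 ± 12397 CPM (SD, n = 7) on HFHS, a log2 change of -0.06 ± 0.20 (SE). The fatty acid desaturase gene Scd1 differed by 0.41 ± 0.29 and the apolipoprotein gene Apoe by -0.02 ± 0.17. Transferrin (Trf) and the overlapping Gm20425, which carried almost the same counts, both differed by -0.33 ± 0.16. Adjusted p values of these 5 genes ran from 0.257 to 0.954 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Limma voom with quality weights called Trf and Gm20425 lower, at -0.47 each (adjusted p 0.0127 for both in limma's moderated test). No other alternative called any of the 5.

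The mean scores of genes with sex-biased expression in mouse liver differed in opposite directions, but by edgeR without a block most of the genes were not called. Both lists had adjusted p = 0.646 with an estimated correlation (limma's camera), the highest of their alternatives. Among 22 measured male-biased genes DESeq2 called 11 lower, limma voom 13, the title number block 10 and the pairs of titles 11, and none higher. By edgeR without a block 3 of the 22 fell, 0 rose and 19 were not called, and adjusted over the list alone 15 fell. The genes called lower by edgeR included Gstp1, a glutathione transferase, which went from 311 ± 98.4 CPM (SD, n = 7) to 141 ± 46.7 CPM (SD, n = 7), a log2 change of -1.14 ± 0.22 (SE). Cspg5 fell by 1.74 ± 0.39 and Selenbp2 by 1.00 ± 0.24. The complement gene C6, not called over all genes, differed by -1.15 ± 0.30 and was called with the title number block (0.0348) and without HFHS 4 (0.0450) or LFLS 1 (0.0240) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in a range of 0.00125 to 0.632 over all alternatives. Among 17 measured female-biased genes DESeq2 called 3 higher, limma voom 7, the title number block 6 and the pairs of titles 4, and none lower. By edgeR without a block 4 of the 17 rose, 0 fell and 13 were not called, and adjusted over the list alone 7 rose. Besides Cyp2b9 the 4 called by edgeR were Abcd2, a peroxisomal fatty acid transporter gene (16.2 ± 7.98 to 48.5 ± 14.4 CPM, log2 1.58 ± 0.29), Rtn4, a reticulon gene (0.71 ± 0.13), and Ntrk2, a neurotrophin receptor gene (2.20 ± 0.50). Among number 1 and number 2 libraries Gstp1 changed by -1.40 and -0.81, Cspg5 by -1.84 and -1.57, Selenbp2 by -0.62 and -1.39, Abcd2 by 1.44 and 1.77, Rtn4 by 0.86 and 0.56 and Ntrk2 by 2.09 and 2.51. Cspg5 lost its call without HFHS 2, 5 or 6 or LFLS 2 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0506 to 0.0748), Selenbp2 without HFHS 1, 2, 3, 5, 6 or 7 or LFLS 2, 4, 5 or 7 (0.0613 to 0.09999) and Ntrk2 without HFHS 1, 2 or 5 or LFLS 2, 4 or 7 (0.0501 to 0.0740). Rtn4 was not called by the DESeq2 Wald test (adjusted p 0.214, in a range of 0.00231 to 0.539 over all alternatives), nor Selenbp2 with GC and length offsets (0.0633, in a range of 0.00574 to 0.438, edgeR quasi-likelihood, Benjamini-Hochberg). Male-biased members include Mup, Cyp4a12, Cyp2d and Ugt2b genes, whose near-identical copies make single values uncertain.

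The mean log2 CPM over male-biased genes was 7.45 ± 0.48 (SD, n = 7) on LFLS and 6.15 ± 1.02 (SD, n = 7) on HFHS, a difference of -1.30 with an adjusted p of 0.0392 in an exact permutation test, Benjamini-Hochberg adjusted over 28 lists. The female-biased score went from 3.02 ± 0.40 to 4.07 ± 0.50, a difference of 1.05 with the same adjusted p of 0.0392 by the exact permutation test. Differences within title numbers 1 and 2 were -1.11 and -1.54 for male-biased genes and 1.22 and 0.82 for female-biased genes, where exact permutation cannot give a p below 0.0286 and 0.1. With title number as a block the adjusted p values were 0.0400 and 0.0200 by exact permutation. Both lists had adjusted p = 0.646 with an estimated correlation (limma's camera), the highest of their alternatives, which started at 0.0245 and 0.00816. The male-biased call was lost without HFHS 1, 2, 3, 5 or 6 or LFLS 2, 4, 5, 6 or 7 (exact permutation, adjusted p 0.0544 to 0.0914), with a difference of -0.96 without HFHS 1. The female-biased call was lost without HFHS 1 (0.0707), HFHS 5 (0.0816) or LFLS 2 (0.0653).

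**Figure D3:**
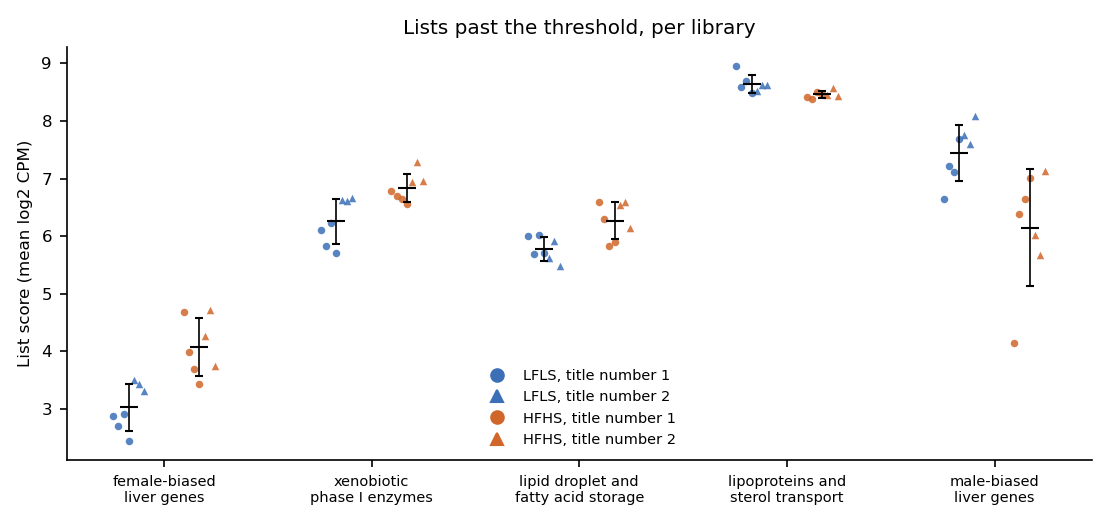
Mean log2 CPM over the members of each list that passed the threshold, per library, with group means, for 7 LFLS and 7 HFHS livers. Male-biased scores average 7.45 on LFLS and 6.15 on HFHS, and female-biased scores 3.02 and 4.07.

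A few genes of lipid droplets and fatty acid storage rose on HFHS and carried the mean of their list, while the median change of its members was 0.05. Of 24 members 4 rose, 0 fell and 20 were not called, and adjusted over the list alone 8 rose and 1 fell. Cd36, the fatty acid translocase, rose from 89.4 ± 25.5 CPM (SD, n = 7) to 263 ± 92.6 CPM (SD, n = 7), a log2 change of 1.55 ± 0.23 (SE). Vldlr and Mogat1 also rose, and the droplet protein gene Cidea rose by 3.11 ± 0.74, from 2.28 ± 2.85 to 20.6 ± 15.2 CPM. Changes among number 1 and 2 libraries were 1.41 and 1.76 for Cd36 and 2.30 and 4.50 for Cidea, which changed by 4.06 without LFLS 3. The mean score rose by 0.49, from 5.78 ± 0.20 to 6.27 ± 0.32 (SD, n = 7), with an adjusted p of 0.0392 in the exact permutation test over 28 lists. Within title numbers 1 and 2 the difference was 0.30 and 0.74, and with title number as a block the adjusted p was 0.0467 by exact permutation. The list had adjusted p = 0.788 with an estimated correlation, and over all alternatives adjusted p ran from 0.0392 to 0.928, the last with the median over members. The call was lost without HFHS 1, 2, 5, 6 or 7 or LFLS 2, 4, 5, 6 or 7 (exact permutation, adjusted p 0.0653 to 0.0938). Cidea lost its call without HFHS 1, 2, 5, 6 or 7 or LFLS 2, 4, 5 or 7 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0532 to 0.0792) and with limma voom (0.108), in a range of 0.00959 to 0.512 over all alternatives.

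The mean score of phase I enzymes of xenobiotic metabolism was also higher, with a median change of 0.40. Of 33 members 4 rose, 1 fell and 28 were not called, and adjusted over the list alone 7 rose and 1 fell. Besides Cyp2b9 and Cyp2b10, Cyp2c38 rose from 23.4 ± 9.46 CPM (SD, n = 7) to 74.4 ± 19.4 CPM (SD, n = 7), a log2 change of 1.67 ± 0.24 (SE). Aldh1a1, which oxidises retinaldehyde, rose from 1056 ± 145 to 1764 ± 185 CPM, a change of 0.74 ± 0.11. Cyp2c38 changed by 1.58 and 1.81 and Aldh1a1 by 0.74 and 0.76 among number 1 and 2 libraries. Aldh1a1 was not called by the DESeq2 Wald test (adjusted p 0.161, in a range of 0.000336 to 0.556 over all alternatives). The called decrease was Cyp1a2, a target of the aryl hydrocarbon receptor, named here after its values were seen, which fell by 0.87 ± 0.17. The mean score rose by 0.58, from 6.25 ± 0.39 to 6.84 ± 0.25 (SD, n = 7), with an adjusted p of 0.0392 in the exact permutation test. Within title numbers 1 and 2 the difference was 0.70 and 0.43, and with the block the adjusted p was 0.0200 by exact permutation. The list had adjusted p = 0.788 with an estimated correlation, in a range of 0.00816 to 0.788 over all alternatives. It shared 7 members with the female-biased list, and without members held by another list its difference was 0.33 and its adjusted p 0.193 by exact permutation. The call was lost without HFHS 1, 2, 3, 5, 6 or 7 or LFLS 2, 4 or 6 (exact permutation, adjusted p 0.0555 to 0.0979).

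The mean score of lipoprotein and sterol transport genes was lower, with a median change of -0.16. Apom, an apolipoprotein of high density lipoprotein, fell from 124 ± 16.3 CPM (SD, n = 7) to 66.7 ± 15.1 CPM (SD, n = 7), a log2 change of -0.89 ± 0.14 (SE), and by -0.78 and -0.997 among number 1 and 2 libraries, and was the 1 called gene among 22 members. Adjusted over the list alone 6 fell and 0 rose. Scarb1, the receptor for high density lipoprotein, differed by -0.56 ± 0.15, Apoa1 by -0.54 ± 0.17 and Apoa5 by -0.53 ± 0.15. With the title number block Scarb1 (0.00948) and Apoa5 (0.0278) were called, and Scarb1 was also called without LFLS 5 (0.0391) or LFLS 6 (0.0193), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over all alternatives adjusted p ran from 0.00342 to 0.693 for Scarb1 and from 0.0278 to 0.637 for Apoa5. The mean score fell by 0.18, from 8.64 ± 0.16 to 8.46 ± 0.06 (SD, n = 7), with an adjusted p of 0.0392 in the exact permutation test. Within title numbers 1 and 2 the difference was -0.24 and -0.11, and with the block the adjusted p was 0.0467 by exact permutation. The list had adjusted p = 0.646 with an estimated correlation, in a range of 0.0367 to 0.646 over all alternatives. With GC and length trends removed the difference was -0.13 (adjusted p 0.131, exact permutation), and with library totals alone the adjusted p was 0.223. The call was lost without HFHS 1, 2, 3, 5 or 7 or LFLS 2, 6 or 7 (exact permutation, adjusted p 0.0555 to 0.0914).

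**Figure D4:**
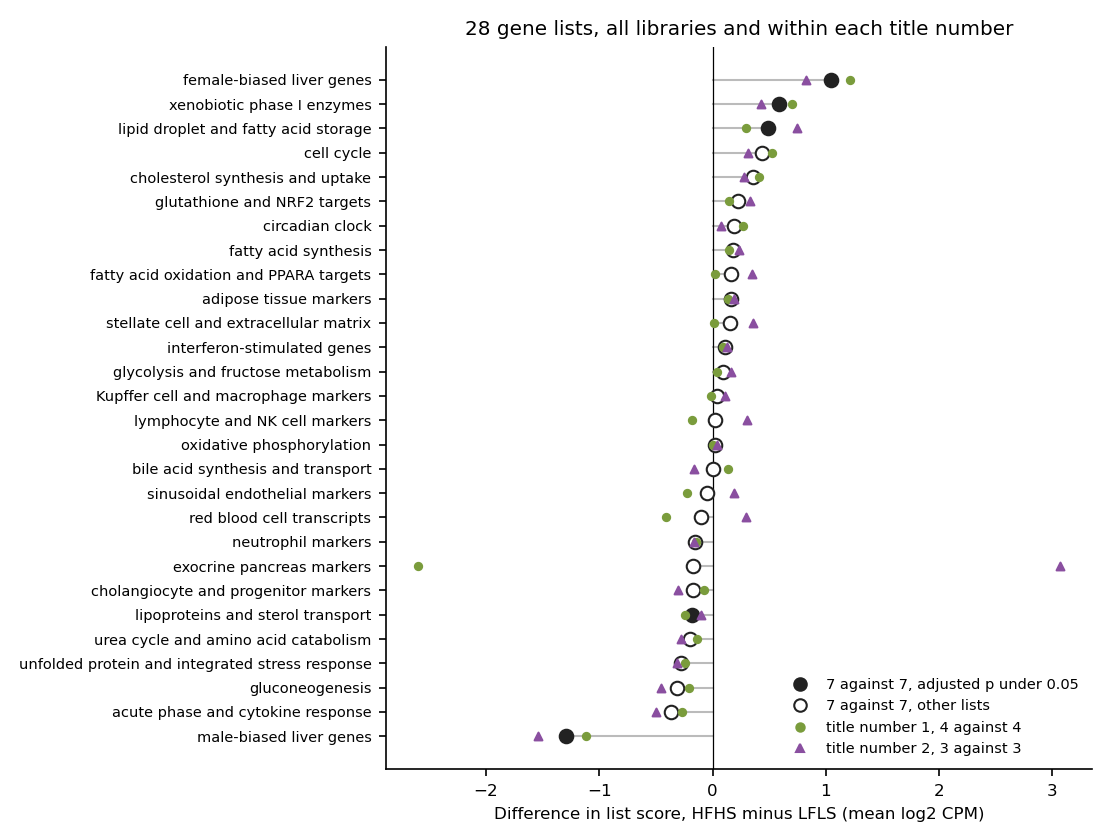
Difference in mean log2 CPM, HFHS minus LFLS, of the 28 gene lists, pooled and within title numbers 1 and 2. The 5 lists past the threshold are female-biased (1.05), xenobiotic phase I (0.58), lipid storage (0.49), lipoprotein (-0.18) and male-biased (-1.30) genes.

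Glucose and amino acid metabolism held 3 called genes, all lower. Of 16 gluconeogenesis genes 1 fell, and adjusted over the list alone 4 did. The called gene was Irs2, an insulin receptor substrate and not an enzyme of the pathway, which went from 30.3 ± 9.20 CPM (SD, n = 7) to 13.5 ± 3.55 CPM (SD, n = 7), a log2 change of -1.17 ± 0.20 (SE), and of -1.13 and -1.19 among number 1 and 2 libraries. Pck1, the phosphoenolpyruvate carboxykinase gene, differed by -0.83 ± 0.26, with adjusted p values of 0.0912 without and 0.00537 with the title number block (edgeR quasi-likelihood, Benjamini-Hochberg), in a range of 0.00537 to 0.516 over all alternatives. The list score differed by -0.31, with an adjusted p of 0.243, and of 0.0467 with the block, both by exact permutation. It had adjusted p = 0.794 with an estimated correlation, and 0.0467 to 0.794 was the range over all alternatives. Of 30 urea cycle and amino acid catabolism genes 2 fell, 0 rose and 28 were not called, and adjusted over the list alone 7 fell and 1 rose. Agxt, the alanine-glyoxylate aminotransferase gene, fell by 0.71 ± 0.14 and Sdsl, a serine dehydratase-like gene, fell by 1.08 ± 0.24. Sdsl lost its call without HFHS 2, 5 or 7 or LFLS 7 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0545 to 0.0656). Cps1, of the first step of the urea cycle, stood at 4340 ± 1550 and 2413 ± 456 CPM, a difference of -0.85 ± 0.22, and was called with the title number block (0.00997) and without LFLS 1 (0.0430) or LFLS 3 (0.0218) by the same edgeR test with Benjamini-Hochberg adjustment, in a range of 0.00997 to 0.512 over all alternatives. Sdsl had 0.0624 with GC and length offsets (edgeR quasi-likelihood, Benjamini-Hochberg), in a range of 0.00519 to 0.395. Changes among number 1 and 2 libraries were -0.74 and -0.62 for Agxt, -0.68 and -1.44 for Sdsl, -0.54 and -1.09 for Cps1 and -0.88 and -0.78 for Pck1. Their score differed by -0.20 (adjusted p 0.320, exact permutation). None of 19 glycolysis and fructose metabolism genes was called by edgeR or DESeq2, 3 had an unadjusted p under 0.05, limma voom called 5 (4 higher, 1 lower) and the block called 1. The glycolysis list differed by 0.09 (adjusted p 0.631, exact permutation).

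Pathways of lipid synthesis and oxidation did not pass as lists. Of 24 cholesterol synthesis and uptake genes 2 rose, Sc4mol by 1.16 ± 0.28 and Sc5d by 0.49 ± 0.13 (log2, SE, n = 7 per diet), and adjusted over the list alone 2 rose. Sc4mol lost its call without any 1 of HFHS 2 to 7 or LFLS 1, 2, 3, 4, 5 or 7 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0526 to 0.0862), and Sc5d without any 1 HFHS library or LFLS 2, 3, 4, 5 or 7 (0.0544 to 0.112). Of 37 genes of fatty acid oxidation and PPARA targets 2 rose, and adjusted over the list alone 6 did. Hadh, a dehydrogenase of beta-oxidation, rose by 0.55 ± 0.12 and the thioesterase gene Acot4 by 1.11 ± 0.28. Hadh lost its call without HFHS 2 (0.0559) or HFHS 5 (0.0510), and Acot4 without HFHS 1, 2, 4, 5, 6 or 7 or LFLS 1, 2, 3, 4, 5 or 7 (0.05002 to 0.109), by the same edgeR test with Benjamini-Hochberg adjustment. Among number 1 and 2 libraries Sc4mol changed by 1.68 and 0.56, Sc5d by 0.61 and 0.36, Hadh by 0.43 and 0.74 and Acot4 by 1.10 and 1.13. By the DESeq2 Wald test neither Sc5d (adjusted p 0.613, in a range of 0.00231 to 0.749 over all alternatives) nor Hadh (0.584, in a range of 0.00100 to 0.679) was called. Sc5d had 0.281 with GC and length offsets in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Score differences were 0.36 for cholesterol and 0.16 for oxidation genes, with adjusted p values of 0.241 and 0.336 by exact permutation. None of 23 fatty acid synthesis genes was called by edgeR, with or without the block, or by DESeq2, 1 had an unadjusted p under 0.05 and limma voom called 5, all higher. Thrsp differed by 0.89 ± 0.49 and the list by 0.18 (adjusted p 0.578, exact permutation). None of 22 bile acid genes was called by edgeR, 5 had an unadjusted p under 0.05, DESeq2 called 1 lower, limma voom 3 higher and 2 lower, and the block 2 higher. Cyp7b1 differed by -1.30 ± 0.38 and Slco1b2 by 0.56 ± 0.18, called without LFLS 1 (0.0377) and without LFLS 6 (0.0495) by the same edgeR test with Benjamini-Hochberg adjustment. Slco1b2 was also called with the title number block (0.0234, same test), in a range of 0.00471 to 0.786 over all alternatives, and differed by 0.82 and 0.31 among number 1 and 2 libraries. The bile acid list differed by 0.01 (adjusted p 0.956, exact permutation), against a median of -0.04.

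Stress and defence lists also stayed short of the threshold. Of 27 glutathione and NRF2 target genes 2 rose and 2 fell, and adjusted over the list alone 7 rose and 3 fell. Nfe2l2, which encodes NRF2, rose by 0.45 ± 0.10 (log2, SE, n = 7 per diet) and Gsta1 by 1.75 ± 0.44, while Gstp1 fell as given for the male-biased genes and G6pdx fell by 0.64 ± 0.15. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Nfe2l2 lost its call without HFHS 1 (0.0528), HFHS 2 (0.0640) or LFLS 2 (0.0502). Gsta1 lost it without HFHS 1, 2, 5, 6 or 7 or LFLS 2, 3, 4 or 7 (0.0632 to 0.0975) and G6pdx without HFHS 1, 2, 3, 4, 5 or 7 or LFLS 4 or 5 (0.0546 to 0.0890). None of the 3 was called by the DESeq2 Wald test, with adjusted p values of 0.640 (Nfe2l2), 0.0544 (Gsta1) and 0.157 (G6pdx). Nfe2l2 had 0.0551 with GC and length offsets in the same edgeR test with Benjamini-Hochberg adjustment, and limma voom gave Gsta1 0.0523. Over all alternatives the adjusted p ran from 0.00825 to 0.640 for Nfe2l2, from 0.0150 to 0.636 for Gsta1 and from 0.00956 to 0.507 for G6pdx. Among 30 acute phase and cytokine genes DESeq2 called 5 lower, limma voom 16 lower and 1 higher, and the block 3 lower and 1 higher. By edgeR without the block 1 of the 30 fell, and adjusted over the list alone 13 fell and 1 rose. The gene called by edgeR was Itih3, which fell by 0.99 ± 0.23 and lost its call without HFHS 1, 2, 3, 5, 6 or 7 or LFLS 2, 4, 5 or 7 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0522 to 0.0818). Changes among number 1 and 2 libraries were 0.40 and 0.54 for Nfe2l2, 1.74 and 1.81 for Gsta1, -0.69 and -0.54 for G6pdx and -0.89 and -1.09 for Itih3. Serum amyloid A1 (Saa1) stood at 492 ± 514 CPM on LFLS, where libraries ran from 11.02 to 1267 CPM, and at 66.8 ± 30.4 CPM on HFHS, a difference of -2.88 ± 0.85. Its adjusted p was 0.0788 without and 0.0495 with the title number block (edgeR quasi-likelihood, Benjamini-Hochberg), 0.0339 without LFLS 1 and 0.0296 without LFLS 6, in a range of 0.00981 to 0.871 over all alternatives. Reads shared with the similar Saa2 make these values uncertain. None of 28 unfolded protein and integrated stress response genes was called by edgeR, 7 had an unadjusted p under 0.05, DESeq2 called 2 lower, limma voom 1 higher and 7 lower, and the block 5, all lower. None of 27 interferon-stimulated genes was called by edgeR or DESeq2, 7 had an unadjusted p under 0.05, limma voom called 2 lower and the block 1 higher and 1 lower. Score differences were 0.22 (glutathione), -0.37 (acute phase), -0.28 (unfolded protein) and 0.11 (interferon), with adjusted p values of 0.270, 0.508, 0.203 and 0.640 by exact permutation, and the unfolded protein list passed without HFHS 4 (0.0443).

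None of the lists of markers of other cell types passed the test. No gene was called by edgeR among 25 Kupffer cell and macrophage, 16 lymphocyte and NK cell, 5 neutrophil, 27 stellate cell and matrix, 20 sinusoidal endothelial, 15 exocrine pancreas or 7 red blood cell genes, and neither the block nor DESeq2 called any. Marco, a macrophage receptor gene, differed by -1.21 and was called without LFLS 6 (-1.40, adjusted p 0.0306) and among number 1 libraries (0.0428) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in a range of 0.0306 to 0.678 over all alternatives. The endothelial gene Dnase1l3 differed by -0.26, and by -0.53 among number 1 libraries, where it was called (0.0489 by the same edgeR test with Benjamini-Hochberg adjustment, in a range of 0.0489 to 0.965), against 0.23 among number 2 libraries. Limma voom called 2 Kupffer and macrophage genes and 1 stellate and matrix gene, all lower, and none in the other 5 lists. Genes with an unadjusted p under 0.05 numbered 6, 2, 0, 2, 0, 0 and 0. The macrophage gene Mmp12 differed by 2.38 ± 0.72 and Gpnmb by 2.74 ± 0.88 (log2, SE, n = 7 per diet). HFHS 1 carried most of the Gpnmb difference and part of the Mmp12 difference. Without HFHS 1 the differences were 1.21 and 0.59, and among number 2 libraries 0.94 and 0.80. Score differences of these lists were 0.04, 0.02, -0.15, 0.16, -0.05, -0.17 and -0.11, with adjusted p values of 0.946, 0.946, 0.606, 0.804, 0.884, 0.951 and 0.667 by exact permutation. Leaving out 1 library changed the sign of 5 of them, so their direction is not settled. The Kupffer difference was -0.12 without HFHS 1, -0.08 without LFLS 6 and -0.02 without LFLS 7, the stellate one -0.06 without HFHS 1 and the endothelial one 0.02 without LFLS 1. The lymphocyte difference was -0.08 without LFLS 5 and between -0.01 and -0.00 without HFHS 1, 2 or 7 or LFLS 7. The exocrine pancreas difference ran from -0.80 without HFHS 5 to 0.74 without LFLS 2, and was also positive without HFHS 1, 3 or 6 or LFLS 3 or 4. Of 13 cholangiocyte and progenitor genes 1 fell, Tff3, and the list differed by -0.18 (adjusted p 0.243, exact permutation). Of 8 adipose tissue genes 1 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell. Car3, a carbonic anhydrase also abundant in liver, rose from 1135 ± 384 to 2244 ± 290 CPM (0.75 and 1.35 among number 1 and 2 libraries), and Adrb3 fell by 1.16 ± 0.28, a call lost without HFHS 1, 2, 5, 6 or 7 or LFLS 1, 2, 3, 5 or 7 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0515 to 0.0966). Car3 was not called by the DESeq2 Wald test (adjusted p 0.148) or, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, without the filter (0.0573) or among number 1 libraries (0.102), in a range of 0.000714 to 0.522 over all alternatives. The adipose list differed by 0.16 (adjusted p 0.382, exact permutation). None of 19 cell cycle genes was called by edgeR or DESeq2, 5 had an unadjusted p under 0.05, limma voom called 1 and the block 2, all higher. Mki67 differed by 1.07 ± 0.31, and was called without HFHS 4 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0376). The cell cycle list differed by 0.43 (adjusted p 0.117, and 0.0435 without HFHS 4 or 0.0367 without LFLS 5, exact permutation). None of 30 oxidative phosphorylation genes was called by edgeR or DESeq2, 1 had an unadjusted p under 0.05, limma voom called 5 and the block 1, all higher, with a list difference of 0.02 (adjusted p 0.942, exact permutation). Median, mean and score differed in sign for the Kupffer, lymphocyte and oxidative phosphorylation lists.

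Some circadian clock genes differed between title numbers. Of 20 clock genes 7 rose and 2 fell in number 2 on LFLS and 3 rose and 3 fell on HFHS. None of the 20 clock genes was called between diets by edgeR or DESeq2, 5 had an unadjusted p under 0.05, limma voom called 7, all higher, and the block 1 higher and 2 lower. The list differed by 0.19 (adjusted p 0.391, exact permutation). Nr1d1, a transcriptional repressor of the clock, stood at 135 ± 71.7 CPM (SD, n = 4) in number 1 and 12.4 ± 5.52 CPM (SD, n = 3) in number 2 libraries on LFLS, and at 69.6 ± 14.8 and 18.4 ± 3.57 CPM on HFHS. Its log2 differences were -3.40 and -1.92, with adjusted p values of 0.00457 and 0.0163 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cry1 rose by 2.02 on LFLS and 1.75 on HFHS. Arntl, the partner of CLOCK, rose by 1.32 and 1.502, and Bhlhe41 fell by 1.33 and 1.48. Nr1d1, Cry1 and Bhlhe41 were named after their values were seen. Across the 20 clock genes the differences on LFLS and HFHS correlated at 0.93, across genes that are not independent replicates, against 0.42 over all genes. In all, 4831 genes differed between title numbers on LFLS (2710 higher and 2121 lower in number 2) and 94 on HFHS (75 higher and 19 lower). With GC and length offsets these numbers were 1926 and 144. The diet effect differed between title numbers for 152 genes by the test of the interaction and for 6 with the offsets, and 4 of 60 regroupings of the title numbers, the real one included, gave as many genes. Those regroupings also break up the difference between title numbers itself, so they cannot decide on chance here.

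**Figure D5:**
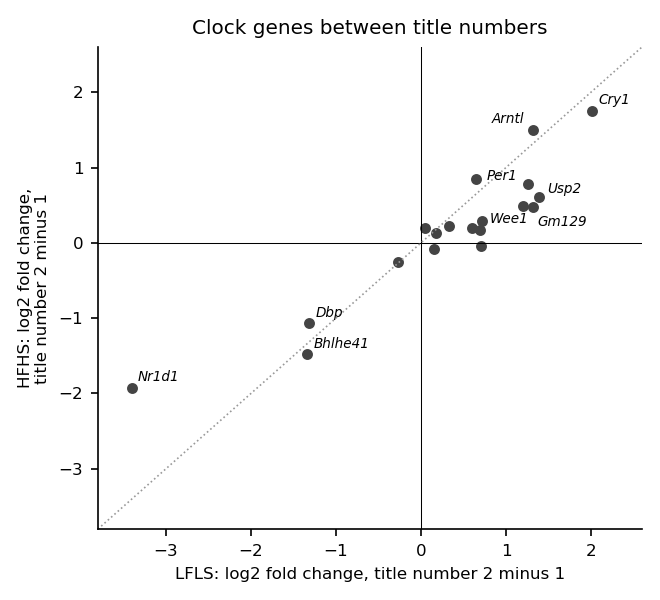
Log2 difference between title numbers 2 and 1 on LFLS and on HFHS, a point per clock gene with 1 gene left out. Nr1d1 lies lowest on both axes at -3.40 and -1.92, and Cry1 highest at 2.02 and 1.75.

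The authors' deposited table held 37 genes with an adjusted p under 0.05 between the diets by DESeq, 17 higher and 20 lower on HFHS. Of these genes of the authors' deposited table, 33 also passed edgeR's quasi-likelihood test here, all 33 in the same direction. The authors' deposited table listed 1013 genes at an unadjusted p under 0.05.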

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

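The tests of clock genes and of Xist counts were chosen only after the result was seen, and the GC and length settings were added after seeing the data. Among 336 groups of 7 libraries, each a named gene, a list score or a library measure within 1 diet, 16 (4.76%) had a library lying far from the other 6 relative to the range of the group, and chance alone gives about 1 in 20. Of the 16 values 8 belonged to HFHS 1 and 3 to LFLS 1, so they are not spread evenly over the libraries. Against the other HFHS libraries, macrophage, stellate cell and endothelial transcripts were high in HFHS 1 and albumin was low. Alb lay lowest at 15.51 log2 CPM, which is 46781 CPM against 66741 to 85518 CPM in the other HFHS libraries. The lipase gene Lpl was highest at 5.44 (43.3 CPM against 9.98 to 17.6), the macrophage gene Gpnmb at 3.93 (15.2 against 0.228 to 1.09), the endothelial gene Gpr182 at 4.89 (29.6 against 19.8 to 21.8) and the matrix gene Dcn at 7.79 (221 against 137 to 166). The scores of Kupffer cell and macrophage markers (4.11 against 2.84 to 3.35), stellate cell and matrix genes (4.94 against 3.10 to 3.74) and sinusoidal endothelial markers (5.59 against 4.97 to 5.13) were also highest there. On LFLS Gpr182 ran from 16.3 to 45.3 CPM and the endothelial score from 4.82 to 5.58, so these values did not set HFHS 1 apart from LFLS. What set HFHS 1 apart from the other HFHS libraries was not tested.

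The other outlying values, in log2 CPM, were in LFLS libraries, and highest and lowest here are among LFLS libraries only. LFLS 1 had the highest glycolysis score (7.27) and the lowest Dcn (6.26) and Ifit2 (1.64), an interferon-stimulated gene. The pancreatic elastase gene Cela1 was highest in LFLS 2 at 7.62, and Fabp5 was lowest in LFLS 3 at 3.89. LFLS 5 had the highest osteopontin gene Spp1 (6.10) and the highest cell cycle score (1.84), and the neutrophil gene S100a9 was lowest in LFLS 6 at -1.24.

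The diet effect differed between title numbers for 152 genes by the edgeR test of the interaction (42 with a higher and 110 with a lower effect in number 2), which is why it is given here. The kinase gene Riok2 differed by 0.88 between diets among number 1 and by -0.05 among number 2 libraries, and the synaptic protein gene Clstn3 by 0.06 and 1.47, both chosen after their values were seen. With GC and length offsets 6 genes passed, Riok2 among them and Clstn3 not. Of 60 regroupings of the title numbers within the diets 4 gave as many genes, the real one included, with 152 in the real and 5234 in the highest other. Such regroupings also break up any difference between title numbers that the diets share. They therefore cannot decide for or against chance in the interaction, which stays open. The highest other regrouping kept LFLS 1 to 4 together, and a count several times the real one points to a structure of the LFLS libraries. No list had an interaction past the threshold by exact permutation (0 of 28), and red blood cell transcripts alone had an unadjusted p under 0.05 (0.0163, exact permutation), with a diet difference of -0.41 in number 1 and 0.30 in number 2 libraries. That permutation regrouped title numbers in the same way and has the same limit.

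Chance is unlikely for the diet comparison as a whole, since 2 of 100 splits of the 14 libraries called as many genes. These were the real one with 484 and another with 3320. That other split set LFLS 1 to 4 and HFHS 1, 2 and 4 against the rest and so followed the title number, and its count, several times the real one, points to the title number as a structure of the samples. With the title number as a block the diets differed in 1540 genes and the highest other of 60 splits gave 4. Only 1 of 60 was as large, so chance is unlikely. Between title numbers, 1 of 35 splits was as large on LFLS (4831 genes, highest other 5) and 1 of 35 on HFHS (94 genes, highest other 18). Chance is unlikely in both, but it is not excluded, since 35 splits cannot give a share below 1 of 35.

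The first pattern weighed was the difference between title numbers on LFLS, where 4831 genes and clock genes such as Nr1d1 and Cry1 differed. Between LFLS 1 to 4 and LFLS 5 to 7 there was no overlap in the share of mitochondrial transcripts (1.39 to 3.77 against 4.32 to 4.91%) or in the scores of sinusoidal endothelial markers (5.24 to 5.58 against 4.82 to 4.95) and of stellate cell and matrix genes (3.75 to 3.90 against 2.93 to 3.31), so RNA quality and the share of cell types, which were not tested, stay open. Its log2 changes correlated with GC content at -0.55, and with GC and length offsets 1926 genes (39.9%) were called, between the bounds set for and against a GC and length bias as the whole cause. Clock gene differences on LFLS and HFHS correlated at 0.93 across 20 genes and at 0.93 with the offsets, against 0.42 over all genes. A difference in time of day or feeding at collection would give such a correlation. But Npas2, too low to be tested, went opposite to Arntl and to the direction set for that explanation. Its mean raw counts fell from 29.8 to 6 on LFLS and from 11 to 7 on HFHS. Scaled to library totals, its log2 difference was -1.77 on LFLS but only -0.14 on HFHS, where it hardly changed. Neither explanation can be told apart from other differences between the title numbers, because time of collection and the meaning of the number are not given in the sources used here.

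The second pattern was the lower mean score of male-biased and the higher one of female-biased genes on HFHS. By edgeR 19 of 22 and 13 of 17 of these genes were not called. DESeq2 called 11 of the 22 lower and 3 of the 17 higher, and limma voom 13 and 7. Both lists had adjusted p = 0.646 with an estimated correlation (limma's camera). Female animals in the HFHS group are excluded, since the highest Xist count in an HFHS library was 13 and the lowest Ddx3y count 1698. With GC and length trends removed the male-biased difference was -1.39 (exact permutation p 0.00175) and the female-biased difference 0.96, which argues against GC bias as the whole cause. Without the Mup, Cyp4a12, Cyp2d, Serpina1, Serpina4-ps1 and Ugt2b members 11 male-biased genes remained, at -1.26 (exact permutation p 0.00175). This argues against reads shared within those families as the whole cause. The 11 left, with Gstp1 and Selenbp2 among them, were not tested for reads shared with related genes, so shared reads stay open there. A response of sex-biased expression to the diet remains open as a hypothesis, found and tested in the same libraries, and its mechanism was not tested.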

How the results depend on the processing

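The settings that subtracted 1, left out libraries with a high pancreas score, corrected for GC content and length, used title numbers for lists or dropped shared list members were chosen only after the result was seen. Against 484 genes by edgeR's quasi-likelihood test, DESeq2 called 273 (174 of the 484) and limma voom with quality weights 3274 (474 of the 484). Voom weighted LFLS 1 at 0.191 and HFHS 2 at 2.91, the lowest and highest of the libraries, and whether this caused its higher count was not tested. Without a filter on low counts 173 genes were called, and 73 against a fold change of 1.2. With the title number as a replicate block 1540 were called, with that block and the GC and length offsets 1208, among number 1 libraries 1484 and among number 2 libraries 269. Among the 7 libraries with a pancreas score at or below 0, 6 were called. Leaving out 1 library gave 133 (HFHS 2) to 853 (LFLS 6) genes and 0 to 7 lists. RLE size factors, library totals alone, a filter of at least 1 CPM, the subtraction of 1 and GC and length offsets alone gave 477 to 632 genes. Of the 484 genes RLE kept 475, library totals 378, the filter 448, the subtraction 474 and the offsets 336, and the diet changes correlated with GC content at -0.31 before the offsets. The median log2 change over all genes stayed between -0.02 and 0.04 in these settings, and the cause of the differing counts was not tested.

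Against 5 lists by exact permutation, library totals alone kept 3. No list passed by camera (0, with 1 at an unadjusted p under 0.05), by the median over members (0, with 6), or among number 1 (0, with 2), number 2 (0, with 0) or libraries with a pancreas score at or below 0 (0, with 0), where the smallest possible p values were 0.0286, 0.1 and 0.0571. No list can pass the adjustment at the last 2 of these values. The number of lists was 0 without HFHS 1, HFHS 5 or LFLS 2, 1 without HFHS 2 or LFLS 6, and 2 without HFHS 3, HFHS 6, HFHS 7, LFLS 4 or LFLS 7. It was 7 without HFHS 4 and 4 or 5 without LFLS 1, 3 or 5. All 5 lists had the same adjusted p of 0.0392 by exact permutation, so their calls were tied and a loss can reflect the other lists. Leaving out 1 library, the highest unadjusted p by exact permutation was 0.0117 for male-biased and 0.00291 for female-biased genes. It was 0.0163 for lipid storage, 0.0122 for lipoprotein and 0.0175 for xenobiotic genes. Apart from the pairs of titles, the settings not named here gave 4 to 6 lists.

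The titles also share letters between 1 library of each diet, which the labels do not explain. Deviations within these 7 pairs correlated at 0.26, -0.00, 0.02, 0.14, -0.07, 0.41 and 0.36. In 3 of 7 pairs the LFLS library was closer to its own partner than to any other HFHS library, so they were not taken as pairs. With the pairs as a replicate block 598 genes (328 higher, 270 lower) and 0 lists were called, with 10 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.0729 by exact permutation. The smallest unadjusted p, 0.0156, was the lowest that exact permutation over 7 pairs can give. A list could pass the adjustment only if several lists reached that value together.

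Over 136 named genes and the settings, 3932 combinations were compared. The direction and call held in 3406, the call was lost in 318 and gained in 171, and 37 uncalled values changed sign. For lists 626 of 755 combinations held, 74 lost and 4 gained a call, and 51 uncalled differences changed sign. No called gene or list changed sign (0 and 0). Of the 50 named genes called, DESeq2 lost 8, limma voom 3, the GC and length offsets 4 and no filter 19, and 30 kept their call without any 1 library.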

Other observations

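The tests of the pancreas score against Saa1, of the spread of Saa1 of the lipid storage score against the sex-biased scores and of the sex-biased scores against other lists were chosen only after the result was seen. With title number as a block, several clock genes separated the diets that the test without it left uncalled. Wee1, a kinase gene under clock control, rose by 1.04 on the log2 scale on HFHS, Arntl fell by 1.18 and Nfil3 fell by 0.71. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the blocked adjusted p values were 0.00997, 0.0105 and 0.0180, and over all alternatives they ran from 0.00360 to 0.820 for Wee1, from 0.0105 to 0.685 for Arntl and from 0.0180 to 0.685 for Nfil3. Arntl was lower on HFHS in both title numbers (-1.26 and -1.05), as was Nfil3 (-0.79 and -0.57), while Wee1 was higher (1.35 and 0.66). Among number 1 libraries alone Wee1 (0.0260), Arntl (0.0297) and Nfil3 (0.0388) were called by the same test with Benjamini-Hochberg adjustment, and over all 14 libraries leaving out LFLS 6 called Wee1 (0.0190).

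Several single genes of metabolism and of the stress response passed in the same blocked fit, although their lists did not all pass. Got1, the cytosolic aspartate aminotransferase gene, fell from 426 ± 249 to 168 ± 75.1 CPM (SD, n = 7 per diet) and by 1.22 with the block. The asparagine synthetase gene Asns fell by 1.65, the endoplasmic reticulum chaperone genes Hyou1 and Calr by 0.75 and 0.51, and Ern1, a sensor of unfolded protein, by 0.43. Socs3, an inhibitor of cytokine signalling, fell by 1.16. In the other direction Slc2a2, the glucose transporter gene of hepatocytes, rose by 0.46 and the bile acid enzyme gene Akr1d1 by 0.74, while the proliferation genes Mki67 and Ccna2 rose by 1.07 and 0.61. Values among number 1 and 2 libraries were 1.14 and 0.23 for Akr1d1, 0.94 and 0.19 for Ccna2, -0.65 and -0.11 for Ern1 and -1.04 and -2.44 for Asns. They were -0.97 and -1.52 for Got1, -0.84 and -0.59 for Hyou1, -0.63 and -0.32 for Calr, -1.05 and -1.29 for Socs3, 0.52 and 0.42 for Slc2a2 and 1.17 and 0.95 for Mki67. These 10 genes had blocked adjusted p values from 0.00130 (Got1) to 0.0494 (Slc2a2) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and over all alternatives from 0.00130 to 0.881. With GC and length offsets added to the block, Slc2a2, Akr1d1, Ccna2, Ern1 and Hyou1 were no longer called, while Got1, Asns, Calr, Socs3 and Mki67 were. Without the block and without LFLS 6, Slc2a2, Socs3, Asns, Hyou1, Calr and Ern1 were called (0.0186 to 0.0487), and Mki67 was called without HFHS 4 (0.0376), by the same test with Benjamini-Hochberg adjustment. Socs3 was also called without HFHS 4, LFLS 1 or LFLS 5, Asns without HFHS 4 or LFLS 1, and Slc2a2 without LFLS 1 (0.0240 to 0.0483). As lists, the unfolded protein response had an adjusted p of 0.0650 and the cell cycle one of 0.0571 with the block by exact permutation.

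The third pattern weighed was the wide range of Saa1 among LFLS libraries, from 11.02 to 1267 CPM. GC and length bias is argued against, since the SD of log2 Saa1 on LFLS was 3.02 with the trends removed and 2.95 without, and its rho with the GC correlation of the libraries was -0.29 (exact permutation p 0.556). Carried-over pancreatic tissue cannot be told apart from other sources with 7 libraries, at a rho of 0.571 with the pancreas score (exact permutation p 0.2). The mean absolute deviation of log2 Saa1 was 6.34 times as large on LFLS as on HFHS (SD 2.95 and 0.64, n = 7 per diet), but Saa1 was taken up because of this range, so the ratio decides nothing about the spread between mice. No biological explanation was tested.

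A further hypothesis was that lipid storage genes and sex-biased genes vary together between mice of the same diet. Across the 7 HFHS libraries the lipid storage score rose with the female-minus-male-biased score, with rho 0.893 (permutation p 0.0123, 0.0246 after Benjamini-Hochberg adjustment over 2 relations) and r 0.838 (permutation p 0.0163). HFHS 1 had the highest value of both scores (6.59 and 0.52). Without the 2 libraries farthest out on the lipid storage score, HFHS 3 (5.83) and HFHS 4 (5.90), r was 0.878, but HFHS 1 stayed in. With GC and length trends removed rho was 0.857, and centred on the title number r was 0.920, with only 4 and 3 libraries within a number. Across the 7 LFLS libraries rho was 0.643 (permutation p 0.139, the same after adjustment) and r was 0.639 (permutation p 0.120). There r was 0.365 without the 2 libraries farthest out on the lipid storage score and 0.751 centred on the title number, and rho was 0.643 with the trends removed. The lists share 0 genes. The relation was not particular to lipid storage, since 7 of 25 other lists had an absolute rho of at least 0.75 with the sex-biased score on HFHS. None of these passed adjustment (0, smallest adjusted p 0.0562), but that adjustment was over 25 lists and the one for lipid storage over 2 relations. Glutathione and NRF2 targets had rho 0.964 (permutation p 0.00278). Fatty acid synthesis and sinusoidal endothelial genes had 0.929 each (permutation p 0.00675), also above the 0.893 of lipid storage. Stellate cell and matrix genes, with their highest score in HFHS 1 (4.94) and their lowest in HFHS 7 (3.10), had rho 0.857 (permutation p 0.0238, 0.119 after Benjamini-Hochberg adjustment) and r 0.883 (permutation p 0.00992). Their r was 0.916 without the 2 libraries farthest out on the sex-biased score and 0.942 centred on the title number, and their rho with lipid storage was 0.75. A difference in the share of cell types between the HFHS libraries was not tested and stays open, and the values on LFLS leave the question open too. Whether the relation differs between the diets was not tested.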
